A study of Homo sapiens with 6 samples.

How the data were processed

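RNA-seq libraries were made from U937 cells given DMSO or ethacrynic acid, 3 of each, from 1 µg of total RNA extracted with TRIzol, with a SMARTER mRNA-seq kit, per the labels' protocols. The submitters' processing notes name fastp, HISAT2, StringTie 1.3.4d, edgeR and the genome build GRCh38, with no role or order. The deposited table holds whole-number counts for 61806 Ensembl gene IDs in the 6 libraries, not scaled between them. The annotation release, the strand setting and the way reads became counts are not given in the sources used here.

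Counts of 4 and 8 were more frequent than their neighbours in every library (in control replicate 1, 651 genes had a count of 3, 1306 a count of 4 and 412 a count of 5). A read pair may therefore be worth more than 1 count, and the precision that totals of 57516146 to 68128543 counts would give is an upper limit. Reads of overlapping genes, of antisense pairs and of near-identical copies could have been divided in ways that the table does not show. The counts of each gene given below with such an overlap or a named pseudogene are therefore uncertain. Exon overlaps and named pseudogenes were looked up for the changed genes and those the naming rule took, not for the other genes mentioned.

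Libraries were grouped by the treatment in their labels, and the table's columns were matched to samples by group and replicate number. Gene names were matched for 61757 of the IDs from a table of Ensembl IDs and symbols, and coordinates are those of GENCODE 29 on GRCh38, counted from 1. Genes were kept with filterByExpr (minimum count 10, minimum total 15), which left 19611. Counts were scaled by TMM and tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3 (limma 3.58.1), with the group as the only term, since no label says that replicate numbers tie libraries together. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. SE values of log2 fold changes are the fold change divided by the square root of F. Levels in CPM (counts per 1e6) were computed from the deposited counts with TMM-scaled library sizes, except those of the 3 most abundant genes, which were scaled to the total count alone. The common dispersion was 0.0845, a coefficient of variation of 29.1% between libraries.

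The 30 gene lists were tested with camera from limma on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, with an estimated correlation and with fry, all two-sided and adjusted over the lists. Single values of libraries were compared with exact two-sided permutation tests. Lists, tests and most alternatives were fixed before the data were examined. Alternatives fixed then were RLE, upper-quartile and total count scaling, no filter and a stricter filter (5 CPM in 3 libraries), DESeq2 1.42.0, limma-voom, the replicate number as a term, each library left out in turn, an adjusted p under 0.01 and a test against a 1.5-fold change. Alternatives chosen after seeing the data were counts divided by 4, the bias-adjusted quasi-likelihood method and protein-coding genes only. Gene lists chosen after seeing the data were V-ATPase subunits, autophagy genes, iron handling genes, proteasome subunits, immediate early genes and a separate list of epithelial genes.

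The rule for named genes was also set beforehand. It took the 10 largest rises and 10 largest falls by log2 fold change among genes with an adjusted p under 0.05, a mean of at least 5 CPM over the 6 libraries and groups that did not overlap, leaving out IDs with no gene name, XIST and Y-linked genes. It further took all 19 genes of a fixed panel, up to 4 called members of each list with the smallest p, and the mean levels of the 3 most abundant genes. Genes outside this rule are said to be chosen after their values were seen. Only 6 falling genes met the conditions. Some genes that the rule or the lists include are not reported here, though they remain in the counts.

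The test was run on counts simulated from the control means, library sizes and spread of the real libraries. Of 18877 genes 200 were changed, drawn only from those with a control mean of at least 5 CPM. The recovered shares therefore do not cover genes below that level. For all 6 libraries the test recovered 28.4% of genes changed 1.5-fold, 86.6% of those changed 2-fold and 98.5% of those changed 4-fold. These were 19, 58 and 65 genes, and 13 of 18677 unchanged genes were called beside them. With 5 libraries, leaving out ethacrynic acid replicate 3, the shares were 14.9%, 74.6% and 98.5%. The simulated spread was estimated from all 6 libraries, replicate 3 included. These shares therefore do not measure the power of the real fit without replicate 3, which called 148 genes against 52 with it. No other library was left out in the simulation, so the shares do not cover the other left-out fits either. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and overlaps of exons were found with bedtools 2.31.1.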

Results

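RNA of U937 cells, a human line of monocytic character that the labels list as AML, was sequenced after exposure to ethacrynic acid or to the vehicle DMSO. Ethacrynic acid is a loop diuretic that blocks sodium-potassium-chloride cotransport, reacts with thiols and inhibits the glutathione transferase GSTP1. The comparison addresses how the compound alters transcripts of a myeloid line in a study of differentiation. There were 3 control and 3 ethacrynic acid libraries. Their titles place them at day 3, whereas the treatment note speaks of 2 days of exposure, and no label used here gives a dose. Nothing in the labels says that the replicates were separate cultures, so every p-value measures only the spread between these libraries, which may be technical.

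The 6 libraries held between 57516146 and 68128543 counts. The lowest total among the control libraries was 66907158 counts, and the totals of the ethacrynic acid libraries were 66677543, 57516146 and 62722538 counts. The groups did not overlap in depth, and the exact two-sided permutation p was 0.1, the smallest that 3 against 3 allows. Mitochondrial transcripts led every group, with MT-CO1 at a mean of 20084 CPM, MT-ND4 at 14705 CPM and MT-CO3 at 13658 CPM over the 6 libraries (CPM, here counts scaled to the total alone, without TMM). Replicates of a group differed by more than counting noise, with a chi-square per degree of freedom between 24.2 and 117, so no library appeared to be deposited in duplicate. Ethacrynic acid replicate 3 stood apart on the first principal component of log2 CPM, at 93.9 against -36.9 to -10.4 for the other 5 libraries. This component carried 33.3% of the variance. The second component, with 24.5%, placed every control library above every ethacrynic acid library (exact two-sided permutation p = 0.1, again the smallest possible).

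Of the 19611 genes tested, 45 were higher and 7 lower in the ethacrynic acid than in the DMSO libraries. NGFR, which encodes the p75 neurotrophin receptor (ENSG00000064300, chromosome 17, 49495293 to 49515017), rose from 0.556 ± 0.0110 to 13.1 ± 0.515 CPM (SD, n = 3 each), a log2 fold change of 4.55 ± 0.18 (SE, adjusted p = 0.00013). SLCO2B1, an organic anion transporter (ENSG00000137491, chromosome 11, 75100563 to 75206549), rose from 0.616 ± 0.208 to 12.9 ± 5.04 CPM (log2 fold change 4.39 ± 0.39 SE, adjusted p = 0.0098). S100A9, a subunit of the phagocyte protein calprotectin (ENSG00000163220, chromosome 1, 153357854 to 153361027), rose from 1.15 ± 0.625 to 11.9 ± 4.26 CPM (log2 fold change 3.37 ± 0.46 SE, adjusted p = 0.041). The neutrophil chemokine CXCL8, or interleukin-8 (ENSG00000169429, chromosome 4, 73740506 to 73743716), rose from 4.17 ± 0.836 to 32.9 ± 13.1 CPM (log2 fold change 2.98 ± 0.31 SE, adjusted p = 0.015). The arrestin-domain gene ARRDC3 rose from 4.04 ± 0.116 to 27.2 ± 4.17 CPM (log2 fold change 2.75 ± 0.15 SE, adjusted p = 0.00083). The sulfotransferase gene SULT1C2 rose from 3.45 ± 0.680 to 21.3 ± 6.60 CPM (log2 fold change 2.63 ± 0.26 SE, adjusted p = 0.013). CES1P1, a transcribed pseudogene beside the carboxylesterase gene CES1, rose from 20.9 ± 2.92 to 71.6 ± 18.1 CPM (log2 fold change 1.77 ± 0.20 SE, adjusted p = 0.019). CES1 itself, named here after its values were seen because its reads can be shared with that copy, rose from 306 ± 30.1 to 987 ± 208 CPM (log2 fold change 1.69 ± 0.17 SE, adjusted p = 0.013). The summed counts of CES1 and its 2 pseudogenes were 3.22-fold higher with ethacrynic acid. The division of reads within this family is uncertain, as it is for SULT1C2, which has 2 named pseudogenes. Antisense transcripts are annotated over exons of NGFR and ARRDC3, and without a stated strand setting their reads cannot be told apart.

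Fewer genes fell, and 6 of the 7 met the conditions for naming. TENT5C, a poly(A) polymerase gene (ENSG00000183508, chromosome 1, 117605934 to 117628372), fell from 34.4 ± 7.22 to 12.3 ± 1.07 CPM (SD, n = 3 each; log2 fold change -1.48 ± 0.17 SE, adjusted p = 0.019). F13A1, the A subunit of coagulation factor XIII made by monocytes and platelets (ENSG00000124491, chromosome 6, 6144085 to 6321013), fell from 30.8 ± 2.83 to 13.1 ± 1.84 CPM (log2 fold change -1.23 ± 0.14 SE, adjusted p = 0.019). CX3CR1, the fractalkine receptor of monocytes (ENSG00000168329, chromosome 3, 39263494 to 39281735), fell from 12.7 ± 0.534 to 5.94 ± 0.667 CPM (log2 fold change -1.09 ± 0.15 SE, adjusted p = 0.040). CCDC74A (log2 fold change -1.02 ± 0.15 SE) and the beta-spectrin gene SPTB (-0.98 ± 0.12) fell, with adjusted p values of 0.048 and 0.022. MDGA1, which encodes a membrane-anchored adhesion protein, also fell (-0.87 ± 0.11, adjusted p = 0.031). PLEKHG3 is annotated opposite SPTB, which leaves the counts of SPTB uncertain. The remaining lower gene, ENSG00000188223, had no name in the table used and was chosen after its values were seen. It was listed at 0 counts in each ethacrynic acid library and at 86, 78 and 36 counts in the control libraries. Its exons overlap LIN37 and PSENEN on the same strand, so its counting is uncertain too.

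In these edgeR quasi-likelihood tests with Benjamini-Hochberg adjustment, all 52 changed genes had groups that did not overlap, as had 17.6% of all tested genes, where chance gives 10%. DESeq2 called 511 genes, 342 higher and 169 lower, including all 52. The calls of single genes depended on the libraries: 4, 8 and 7 genes were called without control replicate 1, 2 or 3. Without ethacrynic acid replicate 1, 2 or 3 the counts were 62, 6 and 148. All 52 kept their direction in each of those 6 fits, but only 4 were called in all 6 of them. These were NGFR, ARRDC3, FTH1 and the pseudogene NMRAL2P, the last of which was chosen after its values were seen. Of the genes named so far, the calls of SLCO2B1, S100A9, CXCL8, SULT1C2, CES1P1 and all 6 named falling genes ended without each single control library in turn, with adjusted p values of up to 0.327. All of these except SLCO2B1 also lost their call without ethacrynic acid replicate 2. S100A9 and CCDC74A were also not called without ethacrynic acid replicate 1.

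**Figure D1:**
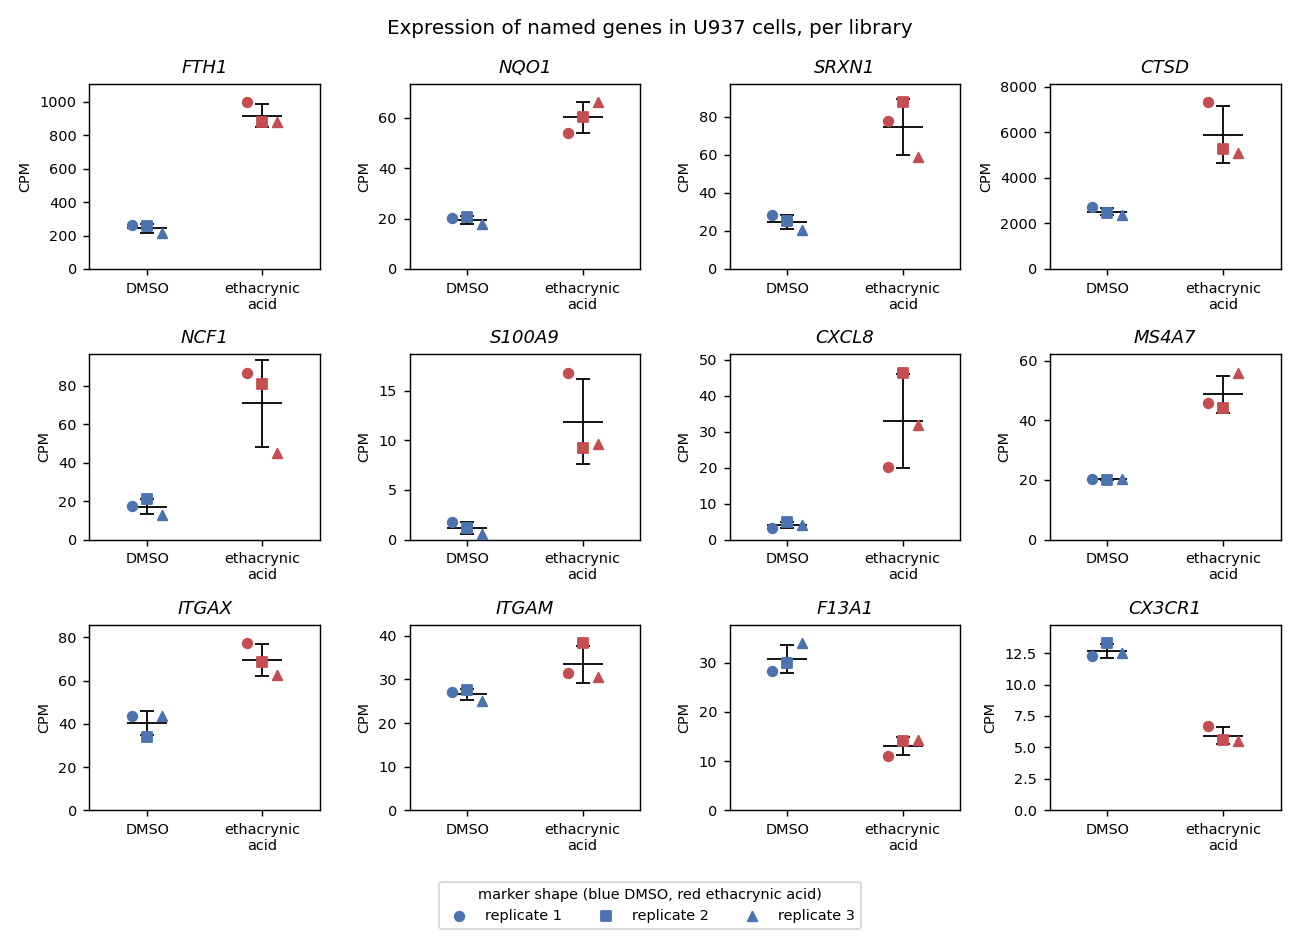
Expression of 12 genes in CPM (vertical axes, starting at 0) in the DMSO (blue) and ethacrynic acid (red) libraries, with a marker shape per replicate number, the mean as a horizontal bar and the SD as an error bar (n = 3). The groups do not overlap in any of the 12 panels, and the integrin genes ITGAX and ITGAM did not pass the test (adjusted p = 0.081 and 0.39).

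Genes controlled by NRF2, the transcription factor of the response to oxidants and electrophiles, were higher as a list. Of 29 tested members 8 rose, none fell and 28 had a positive log2 fold change, with a median of 0.96 (camera, adjusted p = 1.66e-20). This call also held with an estimated correlation (adjusted p = 0.025), and it was the only list of the 30 for which that was so. The count of risen members was 21 when adjusted over the list alone. FTH1, the ferritin heavy chain (ENSG00000167996, chromosome 11, 61959718 to 61967660), rose from 244 ± 27.1 to 918 ± 69.3 CPM (SD, n = 3 each; log2 fold change 1.91 ± 0.12 SE, adjusted p = 0.0011). NQO1, a quinone reductase (ENSG00000181019, chromosome 16, 69706996 to 69726951), rose from 19.5 ± 1.61 to 60.1 ± 6.13 CPM (log2 fold change 1.62 ± 0.12 SE, adjusted p = 0.0033). SRXN1, which repairs oxidised peroxiredoxins, rose from 24.7 ± 3.80 to 74.6 ± 14.6 CPM (log2 fold change 1.59 ± 0.17 SE, adjusted p = 0.018). The pirin gene PIR rose from 16.0 ± 1.13 to 36.8 ± 3.96 CPM (log2 fold change 1.20 ± 0.12 SE, adjusted p = 0.013). OSGIN1, an oxidative stress-induced growth inhibitor, rose from 2.97 ± 0.709 CPM in DMSO (log2 fold change 2.02 ± 0.28 SE, adjusted p = 0.043). The other 3 were chosen after their values were seen. The ferritin light chain FTL rose from 3868 ± 320 to 9524 ± 2305 CPM, the pentose phosphate enzyme PGD from 209 ± 14.4 to 435 ± 81.5 CPM, and the thioredoxin reductase TXNRD1 from 105 ± 6.01 to 204 ± 30.9 CPM. HMOX1, the inducible heme oxygenase, did not pass, at 1.10 ± 0.166 and 2.64 ± 0.727 CPM (log2 fold change 1.27 ± 0.30 SE, adjusted p = 0.20). Nor did the cystine transporter SLC7A11 (0.95 ± 0.20, adjusted p = 0.15) or the glutathione synthesis gene GCLM (0.28 ± 0.17, adjusted p = 0.56). DESeq2 called HMOX1 (adjusted p = 0.019) and SLC7A11 (adjusted p = 9.06e-05). SLC7A11 also passed in the edgeR test without ethacrynic acid replicate 1 (adjusted p = 0.038) and with the replicate number as a term (adjusted p = 0.039).

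Exons of SRXN1 and OSGIN1 overlap another annotated gene on the same strand, and those of FTH1, NQO1 and SLC7A11 one on the other strand, so their counting is uncertain. PGD has 1 named pseudogene. FTH1 and FTL have 25 and 16 named pseudogenes in the annotation used, and the summed counts of each family were 3.74-fold and 2.45-fold higher with ethacrynic acid. The number of NRF2 members that rose was 1 without control replicate 1 and 2 without control replicate 2, control replicate 3 or ethacrynic acid replicate 2. It was 15 without ethacrynic acid replicate 3, and DESeq2 called 18. NQO1 lost its call only without control replicate 1 (adjusted p = 0.057). PIR, SRXN1 and OSGIN1 lost theirs without each control library and without ethacrynic acid replicate 2 (adjusted p of up to 0.135, 0.139 and 0.291). OSGIN1 was also not called without ethacrynic acid replicate 1. The list test held in all 6 such fits, with a highest adjusted p of 2.96e-15.

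The glutathione enzymes, which include the compound's known target GSTP1, were called as higher by camera (20 of 29 positive, median log2 fold change 0.13, adjusted p = 0.049). No member passed among all genes, and MGST1 and GSR, both chosen after their values were seen, rose adjusted over the list alone. GSR is also among the 21 NRF2 targets that rose over their own list alone. DESeq2 called 2 glutathione enzymes as higher. The camera call was lost with an estimated correlation (adjusted p = 0.57), under total count scaling (adjusted p = 0.076) and with protein-coding genes only (adjusted p = 0.073). It was also lost without control replicate 2, control replicate 3 or ethacrynic acid replicate 1 (adjusted p = 0.17, 0.13 and 0.32), and the median was 0.07 without control replicate 2 and 0.02 without ethacrynic acid replicate 1. GSTP1 was at 1242 ± 130 CPM in control and 1360 ± 361 CPM in ethacrynic acid libraries (SD, n = 3 each; log2 fold change 0.13 ± 0.19 SE, adjusted p = 0.82). Its log2 fold change was -0.09 without ethacrynic acid replicate 1, and 1 named pseudogene leaves its counts uncertain. SLC12A1, the renal cotransporter that loop diuretics block, had 10, 0 and 18 counts in the control libraries and 7, 0 and 0 in the ethacrynic acid libraries, too few to test. Its exons overlap CTXN2 on the same strand. The related cotransporter SLC12A2 was at 8.42 ± 1.55 and 7.07 ± 2.78 CPM (log2 fold change -0.25 ± 0.31 SE, adjusted p = 0.79), with 0.03 without ethacrynic acid replicate 1.

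Among genes of myeloid differentiation, those of the phagocyte NADPH oxidase, the enzyme of the respiratory burst, were higher as a list (5 of 6 positive, median log2 fold change 0.61, camera adjusted p = 0.00055). This was lost with an estimated correlation (adjusted p = 0.38). NCF1, its cytosolic p47 subunit (ENSG00000158517, chromosome 7, 74773962 to 74789315), rose from 17.1 ± 4.05 to 71.0 ± 22.6 CPM (SD, n = 3 each; log2 fold change 2.05 ± 0.27 SE, adjusted p = 0.040). CYBB, chosen after its values were seen, rose as well when adjusted over the list alone. NCF1 is nearly identical to NCF1B and NCF1C, and the summed counts of all 3 went from 38.7 ± 12.2 to 160 ± 55.0 CPM. Monocyte and macrophage markers were higher as a list (15 of 23 positive, median log2 fold change 0.18, camera adjusted p = 0.0011), lost with an estimated correlation (adjusted p = 0.28). The median was 0.29 without ethacrynic acid replicate 1 and 0.11 without replicate 2. In this list MS4A7, a membrane protein gene of monocytes and macrophages, rose from 20.2 ± 0.198 to 48.6 ± 6.31 CPM (log2 fold change 1.27 ± 0.12 SE, adjusted p = 0.010). Its exons overlap MS4A14 on the same strand, which leaves its counts uncertain. Adjusted over the list alone, 7 members rose and FCGR2A, chosen after its values were seen, fell. The integrin gene ITGAX, which encodes CD11c, was at 40.3 ± 5.49 and 69.4 ± 7.28 CPM (log2 fold change 0.78 ± 0.13 SE, adjusted p = 0.081). ITGAM, which encodes CD11b, was at 26.6 ± 1.26 and 33.4 ± 4.17 CPM (0.33 ± 0.12, adjusted p = 0.39). The lipopolysaccharide coreceptor gene CD14 was at 0.232 ± 0.109 and 0.939 ± 0.0723 CPM (2.01 ± 0.46, adjusted p = 0.19). The receptor gene CSF1R had a log2 fold change of 0.05 ± 0.51 SE (adjusted p = 0.98) that was negative under total count scaling (-0.03). ITGAX passed with DESeq2 (adjusted p = 1.90e-05), with a stricter filter on low counts (adjusted p = 0.039) and without ethacrynic acid replicate 3 (adjusted p = 0.037). ITGAX also passed with the replicate number as a term (adjusted p = 0.031). CD14 passed with DESeq2 (adjusted p = 0.031). The numbers of members that rose, 1 in each of these 2 lists, went to 0 without each control library and without ethacrynic acid replicate 2. There the calls of NCF1 and MS4A7 ended, with adjusted p values of up to 0.218 and 0.123. The oxidase and monocyte counts were 0 and 2 without ethacrynic acid replicate 1, 3 and 4 without replicate 3, and 3 and 6 with DESeq2, which also called 1 monocyte marker as lower.

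Granulocyte markers were not called as a list (5 of 12 positive, camera adjusted p = 0.35). Their median log2 fold change was -0.14, while their mean was 0.46 and the test pointed up, and the median lay between -0.14 and 0.13 when each library was left out. S100A9 rose, and adjusted over the list alone S100A9 and MMP9 did. Azurophil granule genes were higher as a list (9 of 12 positive, median log2 fold change 0.33, camera adjusted p = 0.010), but not with an estimated correlation (adjusted p = 0.57) or without ethacrynic acid replicate 1 (adjusted p = 0.12). None of them passed among all genes. Adjusted over the list alone PRTN3, CTSG, RNASE2, RNASE3 and SERPINB1 rose and MS4A3 fell. These 6 genes and MMP9 were chosen after their values were seen. DESeq2 called 2 granulocyte markers and 3 azurophil granule genes as higher, and without ethacrynic acid replicate 3 each list had 2. Stem and progenitor genes were lower as a list (12 of 14 negative, median log2 fold change -0.24, camera adjusted p = 0.049). No member of that list passed among all genes, and adjusted over the list alone MEIS1, chosen after its values were seen, fell and MYC rose. DESeq2 called 1 member as higher and 1 as lower, and 1 fell without ethacrynic acid replicate 3. The stem and progenitor call was lost with an estimated correlation (adjusted p = 0.65), under total count scaling (adjusted p = 0.076) and with a stricter filter (adjusted p = 0.18). It was also lost without control replicate 3, ethacrynic acid replicate 1 or ethacrynic acid replicate 2 (adjusted p = 0.35, 0.27 and 0.097), with medians of -0.09, -0.12 and -0.15, while the median was -0.37 without ethacrynic acid replicate 3. MHC class II genes (8 of 10 negative, median -0.19, adjusted p = 0.34) and retinoic acid response genes (10 of 13 positive, median 0.07, adjusted p = 0.41) were not called. No member of either rose or fell, also adjusted over the list alone. The MHC class II list was called as lower without control replicate 2 (adjusted p = 0.039). Its median was -0.41 without ethacrynic acid replicate 3 and -0.02 without replicate 2, and the median of the retinoic acid list was -0.02 under total count scaling and 0.00 to 0.22 when each library was left out.

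Myeloid transcription factors were not called. The log2 fold changes were 0.37 ± 0.20 for SPI1 (SE, adjusted p = 0.52), 0.30 ± 0.14 for CEBPA (adjusted p = 0.47), 0.30 ± 0.09 for CEBPB (adjusted p = 0.30) and 0.27 ± 0.19 for CEBPE (adjusted p = 0.62). The retinoic acid receptor gene RARA was at 34.2 ± 1.72 and 34.3 ± 5.30 CPM (SD, n = 3 each; adjusted p = 1.00), with a log2 fold change of 0.00 ± 0.13 SE and of -0.08 under total count scaling. The granule peroxidase gene MPO was at 2.94 ± 0.469 and 2.22 ± 0.428 CPM (log2 fold change -0.41 ± 0.25 SE, adjusted p = 0.57). MYC was at 241 ± 35.2 and 344 ± 31.6 CPM (log2 fold change 0.52 ± 0.13 SE, adjusted p = 0.22). CDKN1A, the inhibitor of cyclin-dependent kinases known as p21, was at 10.3 ± 1.33 and 21.9 ± 4.34 CPM (1.09 ± 0.18, adjusted p = 0.076). DESeq2 called MYC (adjusted p = 0.012) and CDKN1A (adjusted p = 2.68e-06), and CDKN1A also passed with the stricter filter (adjusted p = 0.036). Both passed in the edgeR test with the replicate number as a term (adjusted p = 0.025 and 0.013). Exons of CDKN1A, CEBPA, CEBPB and RARA overlap genes on the other strand.

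Lysosomal genes were higher as a list, with 20 of 22 positive and a median log2 fold change of 0.35 (camera adjusted p = 8.86e-09), though not with an estimated correlation (adjusted p = 0.18). CTSD, the aspartic protease cathepsin D (ENSG00000117984, chromosome 11, 1752752 to 1764573), rose from 2519 ± 170 to 5889 ± 1248 CPM (SD, n = 3 each; log2 fold change 1.23 ± 0.15 SE, adjusted p = 0.031). CTSA, the protective protein cathepsin A, rose from 284 ± 16.2 to 557 ± 66.8 CPM (log2 fold change 0.97 ± 0.11 SE, adjusted p = 0.019). None fell, and 13 members rose adjusted over the list alone. Both genes lost their calls without each control library and without ethacrynic acid replicate 2, with adjusted p values of up to 0.149 for CTSA and 0.218 for CTSD. DESeq2 called 9 members. The exons of CTSA overlap NEURL2 and PLTP on the other strand and those of CTSD another annotated gene on the same strand, which leaves both uncertain.

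Inflammatory genes moved upward as a list: of 23 NF-kB and cytokine genes 18 were positive, with a median log2 fold change of 0.42 (camera adjusted p = 5.13e-07, and 0.060 with an estimated correlation). Besides CXCL8, the chemokine gene CCL3 rose from 5.01 ± 0.247 to 11.5 ± 1.34 CPM (SD, n = 3 each; log2 fold change 1.20 ± 0.16 SE, adjusted p = 0.035), and none fell. Adjusted over the list alone, 10 rose and IL1RN, chosen after its values were seen, fell. CCL3 lost its call without each library except ethacrynic acid replicate 3, with adjusted p values of up to 0.211. CXCL8 lost its call without each control library and without ethacrynic acid replicate 2 (adjusted p of up to 0.141). The exons of CCL3 overlap an antisense gene. DESeq2 called 4 members as higher. Interferon-stimulated genes were higher as a list (16 of 21 positive, median 0.16, camera adjusted p = 0.0061, and 0.18 with an estimated correlation), with no member past the test among all genes. OAS1, IRF9 and BST2 rose and RSAD2 fell when adjusted over the list alone, all chosen after their values were seen. DESeq2 called 3 members as higher and 1 as lower, and without ethacrynic acid replicate 3 the counts were 1 and 1. The median of the interferon list was 0.33, 0.28 and 0.27 without control replicate 1, control replicate 2 and ethacrynic acid replicate 1.

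Protein folding genes were higher as lists without any single member passing among all genes. All 20 heat shock genes had a positive log2 fold change, with a median of 0.40 (camera adjusted p = 8.77e-09, and 0.28 with an estimated correlation). There were 8 that rose adjusted over the list alone. Of 19 chaperones of the endoplasmic reticulum 18 were positive, with a median of 0.21 (camera adjusted p = 2.97e-05, and 0.18 with an estimated correlation). Adjusted over the list alone 5 rose, HSPA5, HSP90B1, PDIA4, CALR and MANF, chosen after their values were seen. DESeq2 called 6 heat shock genes and 3 of these chaperones as higher, and 1 heat shock gene rose without ethacrynic acid replicate 3. ATF4 targets (17 of 28 positive, median 0.06, adjusted p = 0.26) and metallothioneins (4 of 6 positive, median 0.12, adjusted p = 0.41) were not called by camera. Neither were p53 targets (12 of 20 positive, median 0.11, adjusted p = 0.080) or the BCL2 family (11 of 16 positive, median 0.11, adjusted p = 0.10). In the BCL2 family BCL2A1, an antiapoptotic member, rose from 23.5 ± 0.769 to 56.0 ± 10.4 CPM (SD, n = 3 each; log2 fold change 1.25 ± 0.14 SE, adjusted p = 0.019). That call ended without each control library and without ethacrynic acid replicate 2 (adjusted p of up to 0.143). Adjusted over the list alone, the genes that rose were SLC7A5, SLC7A11 and SLC3A2 for ATF4, MT2A for the metallothioneins, CDKN1A for p53 and BCL2A1. Of these SLC7A5, SLC3A2 and MT2A were chosen after their values were seen, and SLC7A11 is also counted among the NRF2 targets. The p53 list was called without ethacrynic acid replicate 1 (adjusted p = 0.026). Without ethacrynic acid replicate 3 the medians of the p53 and BCL2 lists were both 0.01. The metallothionein median was -0.05 to 0.23 when each library was left out, and that of the ATF4 list was 0.02 to 0.12 and -0.02 under total count scaling. DESeq2 called 3 ATF4 targets, 1 metallothionein and 1 p53 target as higher, and 1 metallothionein rose without ethacrynic acid replicate 3.

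For genes of growth and metabolism, no list had a member that passed among all genes. Cholesterol synthesis genes (23 of 24 positive, median log2 fold change 0.25, camera adjusted p = 0.00049) and glycolysis genes (18 of 20, 0.24, adjusted p = 0.00068) were higher as lists. So were ribosome biogenesis genes (23 of 25, 0.14, adjusted p = 0.0078) and cytosolic ribosomal proteins (39 of 43, 0.12, adjusted p = 0.030). With an estimated correlation all 4 were lost (adjusted p = 0.47, 0.38, 0.65 and 0.74). Ribosomal proteins were also not called under total count scaling (adjusted p = 0.11) or without control replicate 2, control replicate 3 or ethacrynic acid replicate 1 (adjusted p = 0.066, 0.32 and 0.22, the last with the opposite direction). Their median was 0.07 without control replicate 3, -0.04 without ethacrynic acid replicate 1 and 0.22 without ethacrynic acid replicate 3. Ribosome biogenesis genes were not called without control replicate 3, ethacrynic acid replicate 1 or ethacrynic acid replicate 2 (adjusted p = 0.17, 0.092 and 0.095), with a median of 0.08 in the first of these. Genes of DNA replication were not called (25 of 33 positive, median 0.07, adjusted p = 0.11), nor were those of mitosis (10 of 28 positive, median -0.04 and mean -0.01 while the test statistic was positive, adjusted p = 0.93). The nuclear respiratory chain (17 of 26 positive, median 0.10, adjusted p = 0.26) and mitochondrially encoded genes (8 of 13 positive, median 0.07, adjusted p = 0.55) were not called either. Under total count scaling the medians of DNA replication and mitochondrially encoded genes were -0.01 and -0.02. When each library was left out, the medians were 0.01 to 0.12 for DNA replication, -0.08 to 0.04 for mitosis, -0.05 to 0.19 for the respiratory chain and 0.00 to 0.07 for mitochondrially encoded genes. Without ethacrynic acid replicate 3 DNA replication (adjusted p = 0.0077) and the respiratory chain (adjusted p = 0.0086) were called as higher, the former also without control replicate 2 (adjusted p = 0.011). Adjusted over each list alone, PKM rose for glycolysis and CDC20 for mitosis, both chosen after their values were seen, and no other member of these 8 lists rose or fell. DESeq2 called 2 glycolysis genes, 1 cholesterol synthesis gene and 1 mitosis gene as higher, and 1 glycolysis gene rose without ethacrynic acid replicate 3.

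**Figure D2:**
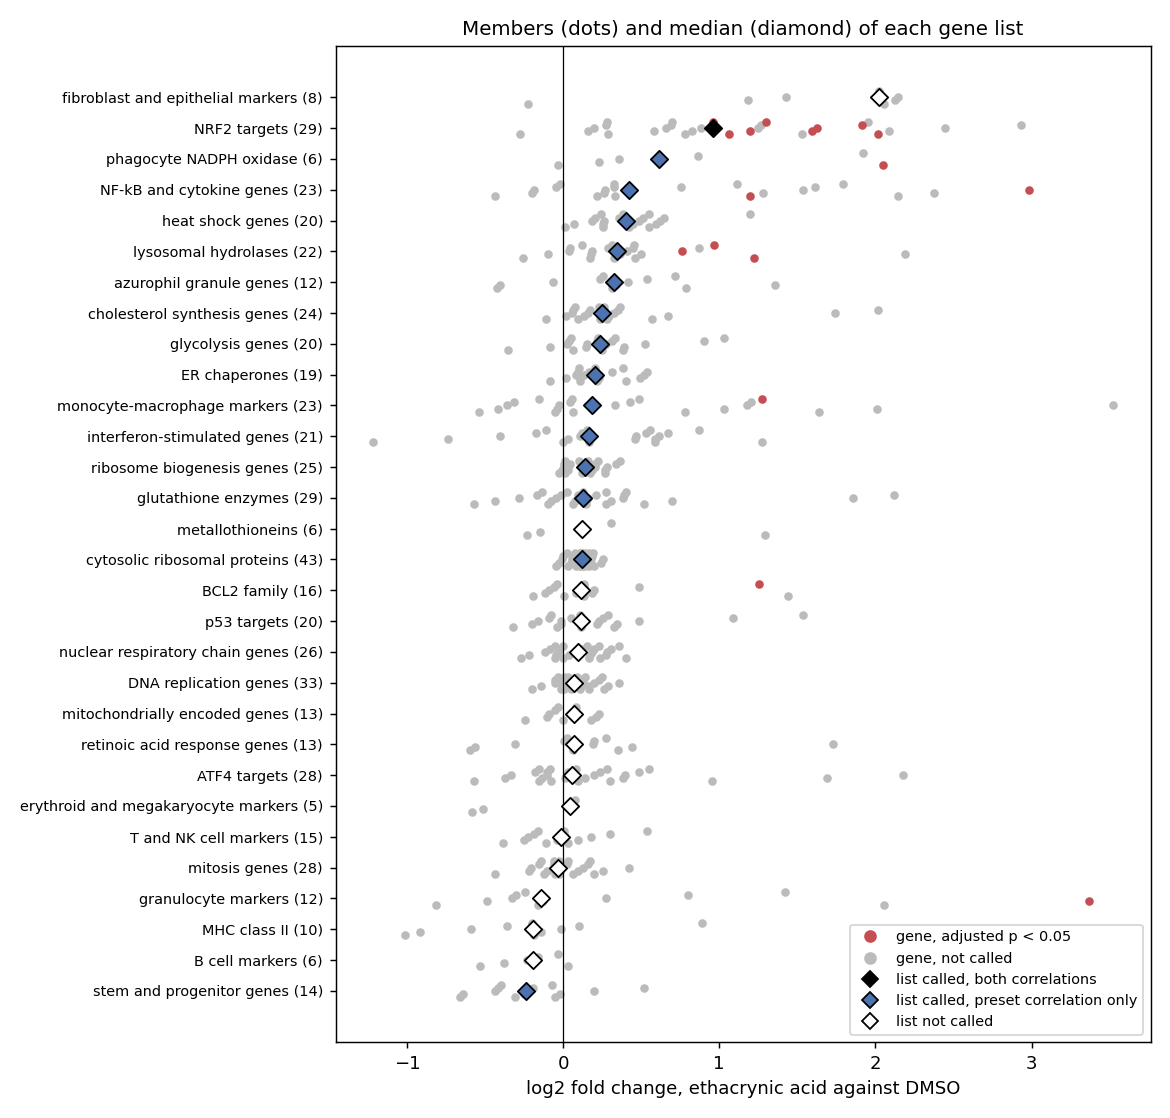
Log2 fold change, ethacrynic acid against DMSO (horizontal axis), of each tested member of the 30 gene lists (dots, red where the gene passed the test) and each list's median (diamond, black where camera called the list with both correlations, blue where only with the preset value), with the number of tested members in brackets. NRF2 targets have the only black diamond, at a median of 0.96.

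Markers of other cell types were read as a check on the libraries. Fibroblast and epithelial markers had a median log2 fold change of 2.02 over 8 tested genes, 7 of them positive, without passing (camera adjusted p = 0.080). The keratin gene KRT8 was at 198 CPM in ethacrynic acid replicate 3 and between 12.7 and 21.7 CPM in the other 5 libraries. EPCAM, an adhesion gene of epithelia, was at 40.9 CPM there and at 2.80 to 5.48 CPM elsewhere. Both genes were chosen after their values were seen. Without ethacrynic acid replicate 3 the median of this list was 0.01 (adjusted p = 0.93), while the list passed without ethacrynic acid replicate 1 (adjusted p = 0.013), without replicate 2 (adjusted p = 0.042) and under total count scaling (adjusted p = 0.032). T and NK cell markers were not called (7 of 15 positive, median -0.01, and -0.23 without ethacrynic acid replicate 1 or 2, adjusted p = 0.93), but without ethacrynic acid replicate 3 they were called as higher (median 0.23, adjusted p = 0.0030). B cell markers (1 of 6 positive, median -0.19, and -0.37 to -0.10 when each library was left out, adjusted p = 0.24) and erythroid and megakaryocyte markers (3 of 5 positive, median 0.04 with a mean of -0.18 and a test pointing down, adjusted p = 0.55) were not called. The erythroid median was -0.05 under total count scaling and between -0.14 and 0.04 when each library was left out. No member of these 4 lists rose or fell, also adjusted over the list alone, while DESeq2 called 1 T and NK cell marker as higher.

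**Figure D3:**
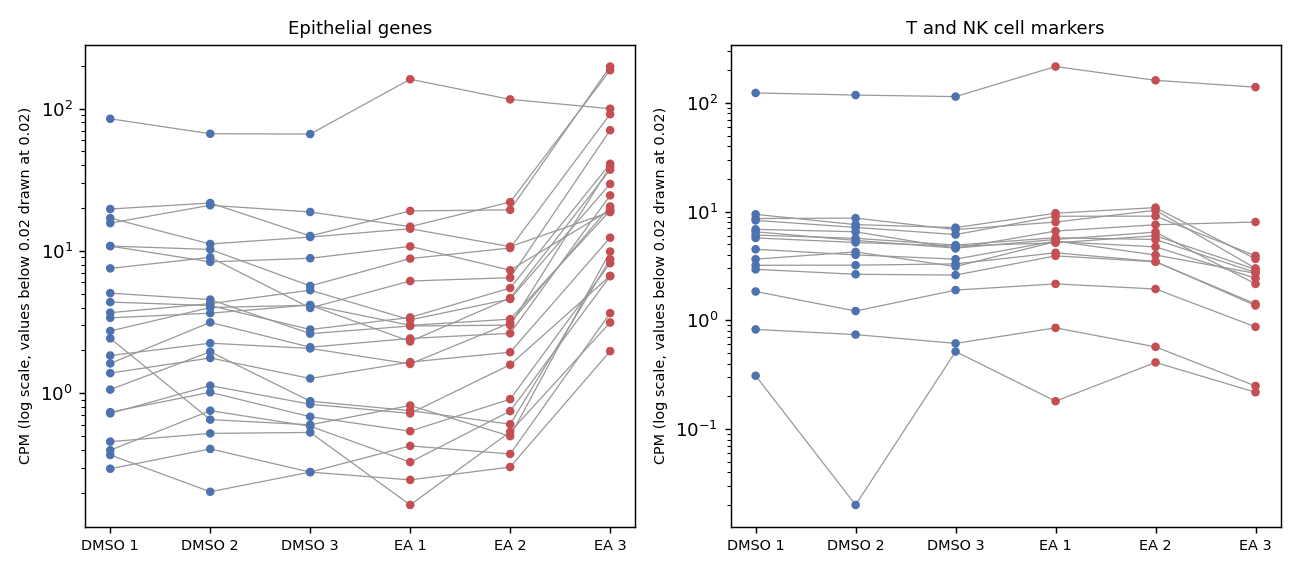
CPM (vertical log axes) of epithelial genes from 2 lists (left) and T and NK cell markers (right) in each library (horizontal axis; EA, ethacrynic acid), with a dot per gene and library, blue for DMSO and red for ethacrynic acid, and grey lines joining the dots of a gene. Nearly all epithelial genes are highest in ethacrynic acid replicate 3, with KRT8 at 198 CPM, and most T and NK cell markers are lowest there.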

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

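Counts divided by 4, bias-adjusted quasi-likelihood and protein-coding genes only were chosen after seeing the data. Against 52 changed genes in the report, RLE, upper-quartile and total count scaling called 52, 48 and 50 genes, 51, 48 and 47 of them shared. Calls by limma-voom numbered 52 (49 shared), and those of the 3 added settings 65, 59 and 45 (51, 51 and 45 shared). The count was 14 (14 higher, 0 lower) without a filter, where 33022 genes were tested, 96 (82 higher, 14 lower) with the stricter filter, 511 (342 higher, 169 lower) with DESeq2, 9 at an adjusted p under 0.01 and 10 against a 1.5-fold change. Leaving out a library gave 4 to 148 changed genes, 4 to 120 higher and 0 to 28 lower. The rise without ethacrynic acid replicate 3 is weighed in the closing observations, and the cause of the other shifts was not tested. Total count scaling moved the median of all genes by -0.08, below 0.1. The 25 called named genes kept their direction under every setting that tested them. All 25 kept their call under the stricter filter, DESeq2, counts divided by 4, bias-adjusted quasi-likelihood and without ethacrynic acid replicate 3; without the filter 17 lost it.

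The labels do not say that equal replicate numbers tie libraries together, and the deviations of same-numbered libraries from their group means correlated across genes at 0.16, 0.06 and 0.09, of which only 1 is above 0.1. The numbers were therefore not taken to pair the libraries. Every library nevertheless correlated best with its own number, which is a hint from the data and not from the design, so a shared day or culture stays open. With the replicate block in the model 355 genes changed (247 higher, 108 lower), all 52 among them, and 16 lists were called. ITGAX, MYC, CDKN1A and SLC7A11, not called without the block, passed with it (adjusted p = 0.031, 0.025, 0.013 and 0.039).

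Reversed directions concerned genes with no call. CSF1R (0.05) was -0.0325 with total count scaling, -0.12 with limma-voom, -0.10 with the replicate block and -0.63 to 0.40 leaving out a library. RARA (0.00) was -0.00888 with upper-quartile scaling, -0.0836 with total count scaling, -0.00388 without a filter, -0.00572 with the stricter filter, -0.00238 with DESeq2, -0.00889 with limma-voom, -0.00731 with the replicate block, -0.00484 with protein-coding genes only and -0.10 to 0.11 leaving out a library. GSTP1 went from -0.0919 to 0.28 and SLC12A2 from -0.54 to 0.0299 leaving out a library. Among lists, 15 were called, 1 of them with an estimated correlation. Leaving out a library gave 11 to 18, and 10 of the 15 were called in all 6 such fits. Fry called 8 lists. They were NRF2 targets, NF-kB and cytokine genes, lysosomal genes, interferon-stimulated genes, heat shock genes and chaperones of the endoplasmic reticulum. The others were monocyte and macrophage markers and the BCL2 family, the latter not called by camera (fry adjusted p = 0.011). The unadjusted camera p, adjusted in the report, went from 6.47e-08 to 0.193 for ribosomal proteins (0.132 in the opposite direction without ethacrynic acid replicate 1) and from 0.00101 to 0.677 for T and NK markers (0.00101 upward without ethacrynic acid replicate 3, where the closing observations weigh their level). For the other results here the cause was not tested. Depth may limit what low genes can show, which was not tested: CD14 rested on fewer than 1 CPM in most libraries, and SLC12A1 was too low to test.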

Other observations

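The added lists, the test of a response to ethacrynic acid and the genes named here outside the naming rule were chosen after the results were seen. Tests of the added lists therefore used data already seen, and their p-values were adjusted over those lists alone, without the 30 fixed ones. All 16 tested subunits of the V-ATPase, the proton pump that acidifies lysosomes, had a positive log2 fold change, with a median of 0.42 (camera adjusted p = 1.60e-07, and 0.096 with an estimated correlation). ATP6V0D2, a subunit of macrophages and osteoclasts, rose from 0.201 ± 0.0639 to 1.47 ± 0.330 CPM (SD, n = 3 each; log2 fold change 2.86 ± 0.39 SE, edgeR adjusted p = 0.041). Of 18 autophagy genes 16 were positive, with a median of 0.15 (camera adjusted p = 0.00031, and 0.058 with an estimated correlation), and VMP1, which acts in autophagosome formation, rose from 43.4 ± 2.49 to 94.9 ± 8.42 CPM (log2 fold change 1.13 ± 0.10 SE, adjusted p = 0.0098). Exons of VMP1 overlap MIR21 on the same strand and PTRH2 on the other, and those of ATP6V0D2 an antisense gene, which leaves both uncertain. Iron handling genes were higher as a list (10 of 13 positive, median 0.26, camera adjusted p = 0.00018, and 0.056 with an estimated correlation). FTH1 and FTL, both already counted among the NRF2 targets, were the members that rose.

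Proteasome subunits (25 of 27 positive, median 0.21, camera adjusted p = 4.02e-05, and 0.37 with an estimated correlation) and immediate early genes (15 of 18 positive, median 0.39, camera adjusted p = 4.02e-05, and 0.056 with an estimated correlation) were higher as lists with no member past the test. Other genes that rose were the complement gene C3, from 16.1 ± 3.15 to 52.6 ± 1.98 CPM (SD, n = 3 each; log2 fold change 1.71 ± 0.15 SE, adjusted p = 0.0098), the chemokine receptor gene CXCR4 (0.86 ± 0.09, adjusted p = 0.013), the urokinase receptor gene PLAUR (1.25 ± 0.15, adjusted p = 0.023), the granule proteoglycan gene SRGN (1.26 ± 0.14, adjusted p = 0.019) and MIR223HG, the host of the myeloid microRNA miR-223 (1.37 ± 0.15, adjusted p = 0.016). The polyamine genes ODC1, for synthesis, and SAT1, for catabolism, rose as well, with log2 fold changes of 0.99 ± 0.13 and 1.05 ± 0.11 (adjusted p = 0.033 and 0.013). C3 and SRGN have 1 named pseudogene each, and MIR223HG overlaps MIR223 on the same strand, so their counting is uncertain.

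Ethacrynic acid replicate 3 carried epithelial transcripts. Over 23 epithelial genes its level was a median of 9.91-fold that of the other 5 libraries (quartiles 6.85 and 10.5). KRT8 was at 198 CPM and AGR2 at 186 CPM in replicate 3. All 23 genes were also counted in the other 5 libraries, for instance KRT8 at 12.7 to 21.7 CPM and EPCAM at 2.80 to 5.48 CPM. Whether those reads share an origin with the reads in replicate 3 was not tested. Epithelial reads at a lower level in the other 5 libraries therefore stay open. A response to ethacrynic acid is argued against, since replicates 1 and 2 differed from control by a median of -0.0672 (log2) where replicate 3 differed by 3.31. RNA or reads of epithelial cells in that library is a candidate explanation: of the 17 tested genes of a separate epithelial list, 16 were highest there, and the exception S100P was at 66.2 CPM or more in every library. Extra spread from that library may also lower the count of changed genes, which was 148 without it against 52 with it.

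The median rise of the NRF2 targets could not be put down to this library. If epithelial RNA in ethacrynic acid replicate 3 were its cause, the median log2 fold change of the list would fall by more than 50% without it, but it was 0.889 against 0.96 with it. A median cannot show how much single members owe to that library. A response to ethacrynic acid, the difference the design names, stays open and was not tested apart from the comparison itself.

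T and NK cell genes, typical of lymphocytes, were present at a low level in both groups, for instance CD5 at 8.63 CPM in control replicate 1. NKG7 was at 114 to 216 CPM. The T and NK cell markers varied together (estimated inter-gene correlation 0.65), so they are not separate observations. Of 15 tested markers 12 were lowest in ethacrynic acid replicate 3, where chance would give 2.5, with a median of 0.492-fold of the other 5 libraries. Reads of another sample shared by 5 libraries, and fewer of them in that library, may account for this. Expression by U937 itself that differed in that library remains open, as LCK was highest there and NKG7 was not lowest.

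Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real split, gave as many changed genes. The real split gave 52 and the highest of the others gave 1. The other splits have libraries of both groups on each side, so a group difference adds to their spread and can lower their counts. Their counts are therefore no measure of what chance alone would give. With 10 splits the share cannot fall below 0.1, which is too few to test chance at 0.05.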
